A study of Mus musculus with 29 samples.

How the data were processed

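Single T cells from the spleens of OT-1 mice were profiled by SMART-seq2, a full-length cDNA method in which each cell is lysed and amplified in its own tube. OT-1 mice carry a transgenic T cell receptor that recognises a peptide of ovalbumin (OVA) on a class I MHC molecule. Per the labels, 21 cells had spent 3 h with antigen-presenting cells (APC) that presented OVA and 8 cells had spent 3 h with APC that presented nothing. The 29 cells are named here OVA cell 1 to 21 and nothing cell 1 to 8, and the number is only a name. The labels name no mouse, culture or day, so each group counts as 1 sample.

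The authors deposited TPM values, which are transcript abundances scaled to a fixed total, 1 column per cell. Each column summed to 1000000 over all 54933 entries, which comprise 54838 genes, 92 ERCC spike-in RNAs and 3 transgenes. Because the spike-ins are part of the total, a library with little cellular RNA has low TPM for its genes. The 3 transgenes were listed at 0 in all 29 cells. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.5 and featureCounts 1.6.4 and the builds GRCm38 and mm10, without the role of each. The amount of spike-in RNA and any filter on cells are not given in the sources used here. Gene positions are from GENCODE M21 on GRCm38, in which 54809 of the 54838 genes had the same identifier and chromosome.

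TPM keeps no record of read number, so the depth of each library is unknown. Of all gene entries 97.3% were exactly 0, and 34941 genes were at 0 in every cell. Genes that every cell uses were also at 0 in many libraries, so a 0 may be a failed estimate, and such a gene is described as listed at 0. A gene was called detected at a TPM of at least 1. Genes detected in at least 3 of the 29 cells were kept, which left 3717. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the upper limit that 3 cells of the total allow. Both cover counting error only.

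For each kept gene the mean of log2(TPM + 1) over the nothing cells was subtracted from that over the OVA cells. This scale understates differences of low genes. No test was made, since cells are not replicates and there is 1 sample per group. A gene list was described by the median difference of its kept members and by the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. A median above the 97.5 percentile or below the 2.5 percentile is described as above or below the range of random lists. The percentile describes these libraries and is no p-value, since genes of one cell move together. A list score per cell was the mean of log2(TPM + 1) over the kept members, and OVA cells above every nothing cell were counted.

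The 15 gene lists, the 15 marker lists, the named genes and most alternatives were fixed before the data were examined. Named genes were up to 4 kept members of each list with the largest absolute difference, 12 genes named in advance, and the 12 largest differences each way among genes detected in at least 50% of the cells of the higher group. Mitochondrial genes, pseudogenes and predicted gene models were skipped in that last part. Some genes that this rule names are not reported here. Further sets were added after the values were seen: gene models at the ribosomal RNA locus of chromosome 17, models that copy mitochondrial sequence on chromosome 1, models at repeat loci of chromosomes 2, 9 and 14, the T cell receptor constant genes, and the pair S100a8 and S100a9. Haemoglobin genes were a further added set.

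Alternatives were pseudocounts of 0.1 and 10, no filter or detection in at least 10 cells, rescaling without mitochondrial genes, median-of-ratios size factors over the 11 genes detected in at least 26 cells (mostly mitochondrial and repeat models), medians over cells, subsets of cells, and each cell left out in turn. The median size factor was 0.73 in OVA cells and 2.57 in nothing cells. Dividing by these factors raised the median difference over all kept genes from 0.10 to 0.48. A difference that turns from below to above 0 with size factors may therefore follow from the scaling. Rescaling without spike-ins, rescaling also without mitochondrial and repeat models, and further subsets of cells were chosen after seeing the data. Doublets were not called. Cells were collected singly in tubes, which does not exclude RNA of more than 1 cell in a tube. The labels give no batch. Serial numbers in the sample titles run through all OVA cells first and then all nothing cells. What they stand for is not given, and group cannot be told apart from that order. The calculation was tested on simulated data, with each of the 3717 genes' values shuffled over the cells and known shifts added to the OVA cells. Of 100 unchanged lists of 10 genes 3 lay above and 4 below the random range, and 99 of 100 lists shifted by 1 on the log2 scale lay above it. Each gene was shuffled on its own, which removes the shared movement of genes within a cell. Shifts were added to every OVA value, also those at 0, and only lists of 10 were tried. These rates therefore check the calculation and do not describe the real libraries. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.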

Results

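The transcriptomes of 29 single splenic OT-1 T cells were compared after 3 h with antigen-presenting cells, 21 with APC that presented OVA and 8 with APC that presented nothing. The design asks how gene expression differs between OT-1 cells that met their antigen and those that did not.

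Spike-ins held more than 50% of TPM in 21 of 29 libraries, and the amount of cellular RNA is unknown because the spike-in amount is not given. ERCC spike-ins took 67.8% ± 32.1 of TPM in the OVA group (SD over 21 cells, median 84.9%, range 5.58% to 97.7%) and 72.4% ± 32.5 in the nothing group (SD over 8 cells, median 87.8%, range 14.8% to 99.4%). Spike-ins exceeded 80% of TPM in 14 of 21 OVA cells (66.7%, 95% interval 43.0% to 85.4%) and 5 of 8 nothing cells (62.5%, 24.5% to 91.5%). They exceeded 90% in 5 of 21 OVA cells (23.8%, 8.22% to 47.2%) and 4 of 8 nothing cells (50%, 15.7% to 84.3%). The OVA cells over 90% had 233 to 742 genes detected and the nothing cells over 90% had 92 to 373, so a gene at 0 says little there. A mean of 1206 ± 890 genes was detected per OVA cell (median 855) and of 1500 ± 2128 per nothing cell (median 795), so the groups differed by less than the spread between cells. The nothing group's mean rested on nothing cell 4, with 6385 genes. Without it the difference in genes detected per cell, OVA minus nothing, went from -293 to 404. Mitochondrial genes held 14.4% ± 19.3 of TPM in OVA cells (median 2.80%) and 8.43% ± 15.4 in nothing cells (median 0.422%, or a mean of 3.85% without nothing cell 7). Gene models at the ribosomal RNA locus held 6.10% ± 10.4 (median 1.31%) and 0.302% ± 0.461 (median 0.0786%, or a mean of 0.153% without nothing cell 4). Olfactory and vomeronasal receptor genes, which T cells are not known to use, were detected at 0.580 ± 0.278 times the rate of other protein-coding genes in OVA cells and at 0.997 ± 0.226 times in nothing cells (SD over cells).

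**Figure D1:**
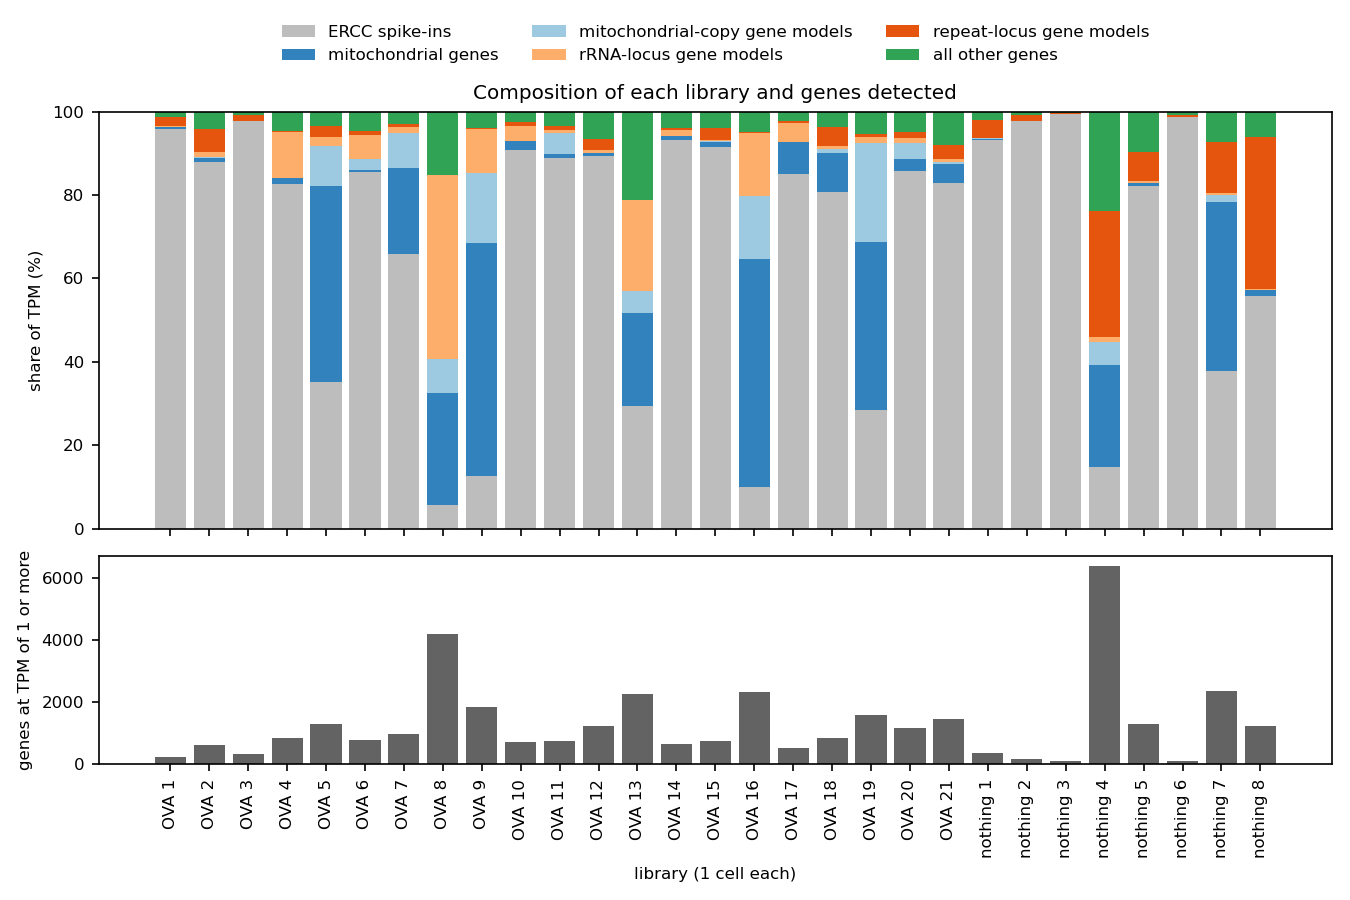
Stacked bars give the share of TPM (%) of spike-ins, mitochondrial genes, 3 kinds of repeat or copy gene models and all other genes in each of the 29 libraries, and the lower bars the number of genes at a TPM of at least 1. OVA cell 8 (4180 genes) and nothing cell 4 (6385 genes) had the most genes, and repeat-locus models held 1.57% of TPM on average in OVA cells and 11.5% in nothing cells.

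Transcripts that identify T cells were found in a minority of the cells. The T cell receptor constant genes Trac, Trbc1 and Trbc2, which encode the invariant parts of the receptor chains, were detected in 4 of 21 OVA cells (19.0%, 95% interval 5.45% to 41.9%) and in 0 of 8 nothing cells, which allows a share of up to 37.5%. OVA cell 13 had the highest levels, with 1009 TPM of Trac (chromosome 14, 54220521 to 54224206), 756 TPM of Trbc1 and 1487 TPM of Trbc2 (chromosome 6, 41546730 to 41548352). OVA cell 9 had 96.2, 64.0 and 250 TPM of the same genes, OVA cell 16 had 24.0 TPM of Trbc2 and 8.42 TPM of Trbc1, and OVA cell 5 had 36.8 TPM of Trac only. Cd8b1, a chain of the CD8 coreceptor, was detected in OVA cell 13 alone (136 TPM), and Cd8a was listed at 0 in all 29 cells. Cd4 was detected in nothing cell 4 alone (30.5 TPM). Trav14d-1 and Trav14n-1, near-identical copies of the variable segment family used by the OT-1 receptor, were at 258 and 303 TPM in OVA cell 13, 47.0 and 54.1 TPM in OVA cell 9, and 133 and 167 TPM in OVA cell 4, with an uncertain split of reads between copies.

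T cell receptor signalling genes lay higher in the OVA group. Of the 11 kept members 10 were higher and 1 lower, and the median difference was 0.67, at percentile 99.5 of matched random lists. Thy1, a T cell surface glycoprotein, was detected in 7 of 21 OVA cells and no nothing cell (difference 1.13), and Lcp2, the adaptor SLP-76, in 4 of 21 and none (1.02). Trbc2 and Trac differed by 1.10 and 1.04, or 0.63 and 0.59 without OVA cell 13. Without OVA cell 13 the median was 0.52, inside the range of random lists. T cell markers also lay higher (4 of 4 kept, median 1.07, percentile 99.96, or 0.61 without OVA cell 13). All 4 (Thy1, Trac, Trbc1 and Trbc2) passed the filter through OVA cells only, so their shared direction is no separate evidence. Without the filter on low values 5 T cell markers were higher and 3 lower (median 0.58, percentile 99.99). These 4 are members of the receptor signalling list, which without them had a median of 0.62 inside the random range (percentile 92). Without the filter on low values that reduced list had 12 members higher and 2 lower, above the random range (median 0.31, percentile 99.59). At the same time 8 of 8 kept housekeeping genes were higher in the OVA group, with a median difference of 1.71 (percentile 99.7, or 96.7 with size factors). Olfactory and vomeronasal receptor genes were detected at 0.580 times the rate of other protein-coding genes in OVA cells and 0.997 times in nothing cells, on average.

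The 10 kept immediate early genes, which are transcribed within minutes of receptor signalling, were all listed at 0 in 5 of 21 OVA cells and 4 of 8 nothing cells. Of these 10 genes 7 were higher and 3 lower in OVA cells, with a median difference of 0.48 inside the range of random lists (percentile 94.1). The median was 0.30 (percentile 75.4) without OVA cell 16 and -0.15 without OVA cells 8, 9, 13 and 16, which were picked for their high scores after seeing the data, so that fall follows from the choice. Ier2 was detected in 8 of 21 OVA cells (38.1%, 95% interval 18.1% to 61.6%) and 0 of 8 nothing cells, Fos in 3 and 0, Jund in 7 and 0, and Jun in 6 and 1. Fos was at 114 TPM in OVA cell 4, 48.6 in OVA cell 14 and 30.4 in OVA cell 16. Egr2, a transcription factor induced by receptor signalling, was at 2.87 TPM in OVA cell 9, 2.40 in OVA cell 16 and 53.4 in nothing cell 5, and Nr4a1, a reporter gene of antigen receptor signalling, was listed at 0 in all 29 cells. On the immediate early genes score, 4 of 21 OVA cells (cells 4, 8, 9 and 16) lay above every nothing cell. OVA cell 8 had 6 of 9 neutrophil markers, with S100a8 at 8910 TPM, and no T cell receptor constant transcript, and 3 cells remained without it. The list median lay above the random range with size factors (percentile 99.3), without the filter on low values (99.98) and without spike-ins (98.0), the last chosen after seeing the data.

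**Figure D2:**
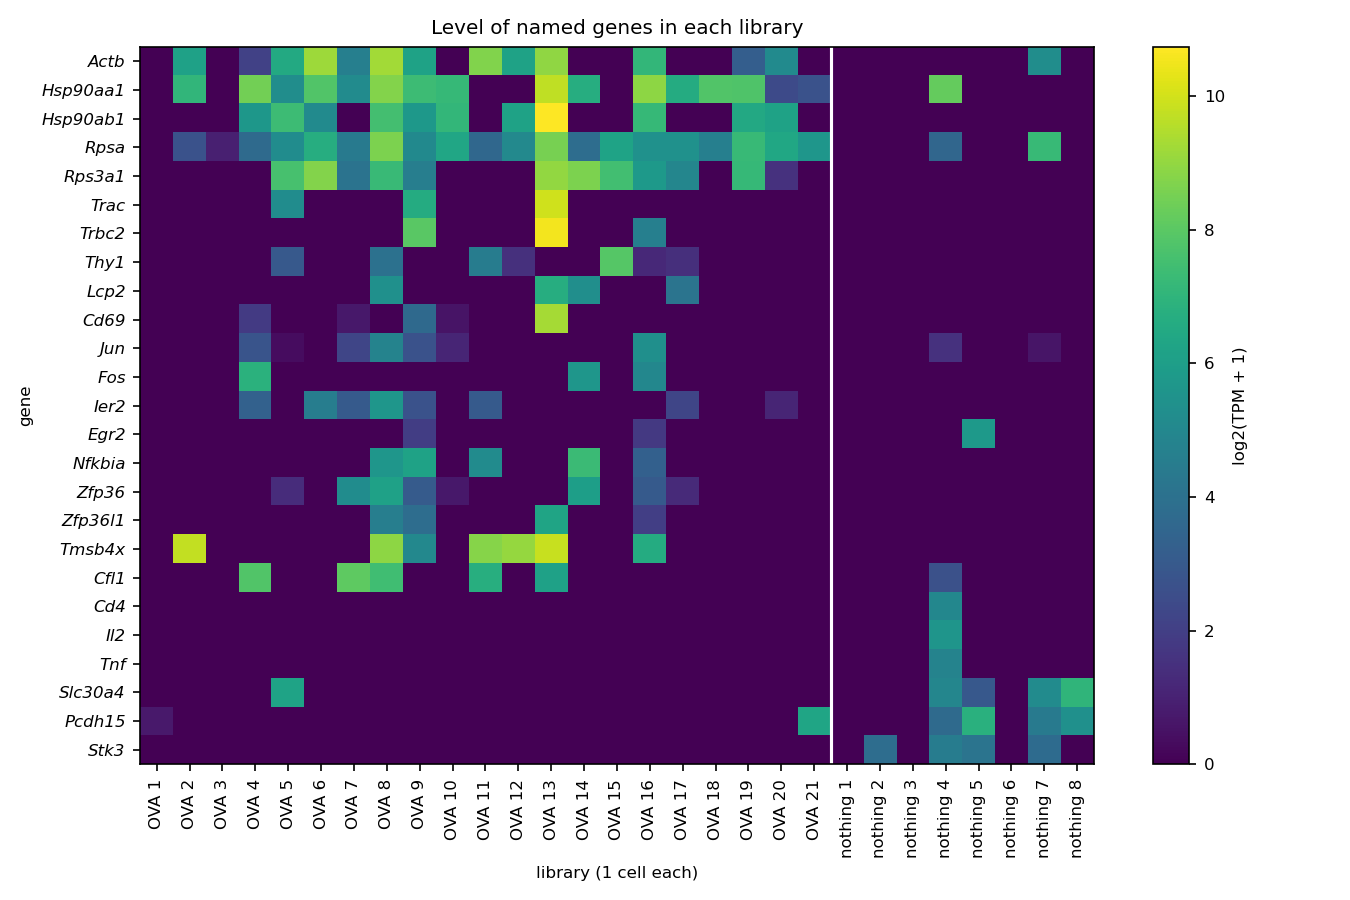
Colour gives log2(TPM + 1) of 25 named genes (vertical axis) in each of the 29 libraries (horizontal axis), with a white line between the OVA and nothing groups. Hsp90aa1 was detected in 16 of 21 OVA cells and 1 of 8 nothing cells, whereas Cd69, Fos and Trac were each detected in 3 OVA cells.

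Early activation surface molecules did not separate the groups. Cd69, a receptor that appears on T cells within hours of stimulation, was detected in 3 of 21 OVA cells (14.3%, 95% interval 3.05% to 36.3%) and 0 of 8 nothing cells (up to 37.5%), at 627 TPM in OVA cell 13, 11.9 in OVA cell 9 and 2.55 in OVA cell 4. Cd44 was detected in 3 and 2 cells (difference -0.45) and Tfrc, the transferrin receptor, in 3 and 1 (-0.11), and both signs turned with size factors (0.36 and 0.40) and without nothing cell 4 (0.08 and 0.55). Size factors also raised the median over all kept genes from 0.10 to 0.48, so the turns under them may follow from the scaling. Il2ra, the high-affinity chain of the interleukin-2 receptor, was detected in OVA cell 11 alone at 5.17 TPM. The median difference of the 3 kept members was -0.11 (percentile 39.8), and it turned to 0.55 without nothing cell 4 (-0.33 without OVA cell 8). On the score, 2 of 21 OVA cells lay above every nothing cell, of which cell 13 had T cell receptor transcripts and cell 8 had neutrophil markers, and leaving out either gave 1.

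Effector transcripts were listed in few cells of either group, as was Gapdh, a glycolytic enzyme of every cell that was chosen after its values were seen and was detected in 4 OVA cells and 1 nothing cell. Ifng was listed at 0 in all 29 cells, and Il2 (48.0 TPM) and Tnf (26.8 TPM) were detected only in nothing cell 4. Mif, a constitutively made cytokine, was detected in 6 of 21 OVA cells and no nothing cell (difference 1.87), and Il21 in 2 and 1 (-0.38, or 0.02 with size factors and 0.36 without nothing cell 4). These were the 2 kept members of the list, with a median of 0.74 (percentile 93.6), or -0.37 without the filter on low values. No cytotoxic granule gene passed the filter, so this list of 12 has no median.

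The 3 kept negative feedback regulators were found in OVA cells and in no nothing cell. All 3 were higher, with a median difference of 1.28 (percentile 99.3), against 1.71 for housekeeping genes (1.38 and 1.18 above the medians of their random lists), of which at least 1 was detected in 18 of 21 OVA cells and 4 of 8 nothing cells. These 3, of 24 listed regulators, passed the filter through OVA cells only, so their shared direction is no separate evidence. Without the filter on low values the negative feedback list lay at percentile 99.99. Nfkbia, which encodes the inhibitor of NF-kappaB, was detected in 5 of 21 OVA cells (23.8%, 95% interval 8.22% to 47.2%), and the mRNA-decay factors Zfp36 and Zfp36l1 in 7 and 4. Nfkbia reached 157 TPM in OVA cell 14 and 72.2 in OVA cell 9, and Zfp36 68.7 in OVA cell 8, the library with neutrophil markers. Among activation transcription factors, Nfkb1 and Rel, both NF-kappaB subunits, were each detected in 4 OVA cells and no nothing cell (differences 0.74 and 0.70). Hif1a differed by -0.06 (0.37 with size factors and 0.41 without nothing cell 4) and Bhlhe40 by -0.02 (-0.39 with size factors, -1.02 without spike-ins and 0.54 without nothing cell 3), and Irf4 and Myc were listed at 0 in all 29 cells. The median of the 4 kept factors was 0.34 (percentile 74.1, or 98.8 without the filter on low values and 43.5 with size factors), and it was 0.62 without nothing cell 3 and 0.56 without nothing cell 4. On their score 4 of 21 OVA cells (cells 3, 8, 9 and 13) lay above every nothing cell, 3 without OVA cell 8 and 8 of 21 without nothing cell 3.

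Chaperone genes, the list with the most kept members, lay higher in OVA cells. Of 14 kept members 13 were higher and 1 lower, with a median difference of 0.90 (percentile 99.8), or 0.55 without OVA cell 13. Housekeeping genes differed by 1.71 in the same libraries. The ratio of olfactory and vomeronasal receptor gene detection to that of other protein-coding genes averaged 0.580 in OVA cells and 0.997 in nothing cells. Hsp90aa1, the inducible cytosolic HSP90 (chromosome 12, 110690605 to 110702728), was detected in 16 of 21 OVA cells (76.2%, 95% interval 52.8% to 91.8%) and in 1 of 8 nothing cells (12.5%, 0.316% to 52.7%), a difference of 4.20. Hsp90ab1, its constitutive counterpart, was detected in 11 OVA cells and no nothing cell (3.58), Hsp90b1 in 5 and none (1.37), and Hspa1a in 9 and 2 (1.31). After OVA cells 8, 9, 13 and 16 were left out, which were picked for their high scores after seeing the data and of which cell 8 had neutrophil markers, the chaperone median was 0.00 (percentile 36.4). No nothing cell was left out with them, so a fall follows from the choice and shows only the weight of these cells.

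Adhesion and migration genes were also higher, 10 of 12 kept members with 2 lower, and the median difference was 0.78 (percentile 98.8), also below that of housekeeping genes. The members with the largest differences encode actin and its regulators. Actb was detected in 13 of 21 OVA cells and 1 of 8 nothing cells (difference 3.31), Tmsb4x and Tmsb10, which bind actin monomers, in 7 OVA cells each and no nothing cell (2.76 and 1.86), and Cfl1, which severs actin filaments, in 5 and 1 (1.39). Leaving out OVA cell 8, the library with neutrophil markers, gave 0.50 (percentile 95.6). The median also lay inside the random range without OVA cell 6 (97.3), OVA cell 7 (97.4) or nothing cell 7 (96.3), with size factors (61.5) and without spike-ins (93.6).

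**Figure D3:**
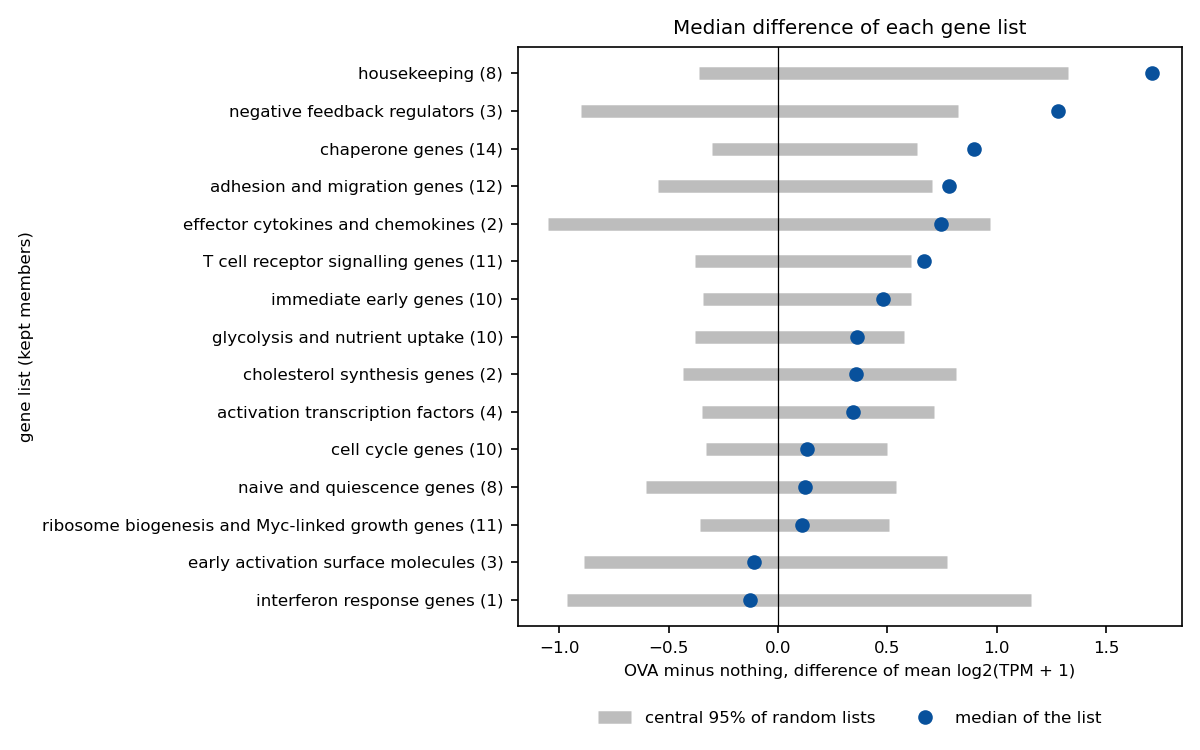
Points give the median difference, OVA minus nothing, of mean log2(TPM + 1) for 14 gene lists and the housekeeping list, with kept members in parentheses, and grey bars the central 95% of matched random lists. Negative feedback, chaperone, adhesion and T cell receptor signalling lists lay to the right of their bars, as did housekeeping genes at 1.71.

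Growth, metabolic and naive-state lists lay inside the random range after the filter on low values. With each cell left out, medians ranged from -0.06 to 0.24 for ribosome biogenesis, 0.22 to 0.54 for glycolysis, -0.01 to 0.39 for cell cycle, -0.18 to 0.48 for naive and quiescence genes and -0.45 to 0.22 for interferon response. Without that filter, glycolysis (percentile 99.5), naive and quiescence (99.6) and cell cycle genes (98.8) lay above it. Ribosome biogenesis genes had a median of 0.11 (11 kept, percentile 49.7), or -0.06 without OVA cell 5, with the nucleolar proteins Npm1 at 1.78 (2.70 without nothing cell 8) and Fbl at 0.96 but Ncl at -1.31, the last turning to 0.30 with size factors and going to -0.36 without nothing cell 8. Glycolysis and nutrient uptake had a median of 0.36 (10 kept, 86.2), or 0.22 without OVA cell 8 and 0.24 without OVA cell 13, with Aldoa, a glycolytic enzyme, detected in 6 OVA cells and no nothing cell (1.91) at ENSMUSG00000030695. A separate Aldoa entry, ENSMUSG00000114515, did not pass the filter and was at 35.1 TPM in nothing cell 4 alone, with an uncertain split of reads between the entries. Cholesterol synthesis genes had 0.36 (2 kept, 71.1), or 0.21 without OVA cell 2 and 0.55 without nothing cell 7, with Srebf2 at 0.66 (0.33 without OVA cell 2), and cell cycle genes 0.13 (10 kept, 61.0), or -0.01 without OVA cell 8, with Mki67 at 0.84 (0.55 without OVA cell 8) and Rrm1 at -0.80 (0.00 with size factors and -0.12 without nothing cell 5). The glycolysis list also lay above the random range after cells under 1000 genes were left out (98.4). Naive and quiescence genes had 0.12 (8 kept, 82.8), or -0.18 without OVA cell 13, with Tcf7 at 0.51 (0.28 without OVA cell 9) and Txnip at -0.70 (-0.23 with size factors and 0.21 without nothing cell 4). On the naive and quiescence genes score 1 of 21 OVA cells (cell 13) lay above every nothing cell. The single kept interferon response gene, Oasl2, differed by -0.13 (percentile 49.6), or 0.31 with size factors, 0.22 without nothing cell 4 and 0.06 without nothing cell 5.

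The 12 genes highest in OVA cells were ranked only among genes that the naming rule allowed, and no theme among them was tested. They included several ribosomal protein genes, but the largest difference was in a gene model at the ribosomal RNA locus. The median difference per gene over the 3717 kept genes was 0.10, and single libraries moved it, to 0.36 without nothing cell 4, 0.25 without nothing cell 7, 0.05 without OVA cell 8 and 0.05 to 0.06 without nothing cell 1, 2, 3 or 6. It was -0.19 without libraries over 90% spike-ins and -0.05 without OVA cells 8, 9, 13 and 16. Besides Hsp90aa1, Hsp90ab1 and Actb, the 12 genes highest in OVA cells included CT010467.1 at the ribosomal RNA locus (chromosome 17, 39846353 to 39848827; difference 4.65), Lars2 (4.04), Mir6236 (group means 8.67 and 4.67), Rpsa (3.68), Rps3a1 (3.66), Rpl12 (2.94), Rps27rt (2.86) and Rps20 (2.85). Rps3a1, a protein of the small ribosomal subunit, was detected in 12 of 21 OVA cells and 0 of 8 nothing cells. Ribosomal protein genes have many processed copies, so reads can be shared between them. The shift of the median over all kept genes was 0.15 after rescaling without spike-ins and 0.38 with size factors. Relative to the all-gene median under each of these, the chaperone list lay at 0.69 and 0.70, against 0.79 as deposited.

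The 12 genes lowest in OVA cells came from no single list and were found in some libraries only. Slc30a4 (a zinc transporter, -2.22), Pcdh15 (a protocadherin of the inner ear, -2.20), Stk3 (-2.02), Fry (-1.88), Akr1b10 (-1.84), Atr (-1.80) and Csmd3 (-1.42) were each detected in 4 of 8 nothing cells (50%, 95% interval 15.7% to 84.3%) and in at most 1 of 21 OVA cells. A share of 50% is the least that the naming rule allows, and the genes were picked for their difference, so these shares are no evidence of one. Sfi1 (-1.81), Atp5l (-1.35), Kansl1 (-1.35) and R3hdm1 (-1.30) were also in this set. With size factors these 11 differences were smaller, from -1.25 (Fry) to -0.18 (Atp5l). Rescaled without spike-ins they were larger, from -3.16 (Fry) to -1.58 (Atp5l). Single libraries moved Atr to -0.96 and Sfi1 to -1.09 (both without nothing cell 8), Atp5l to -0.79 (without nothing cell 7) and R3hdm1 to -0.58 (without nothing cell 5). Pcdh15 spans 73099342 to 74649737 of chromosome 10. In the same libraries, models at repeat loci of chromosomes 2, 9 and 14 took 44.3% ± 23.0 of the TPM outside spike-ins in nothing cells and 14.6% ± 17.1 in OVA cells (SD over cells). The ratio of olfactory and vomeronasal receptor gene detection to that of other protein-coding genes was at least 0.702 in every nothing cell.

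**Figure D4:**
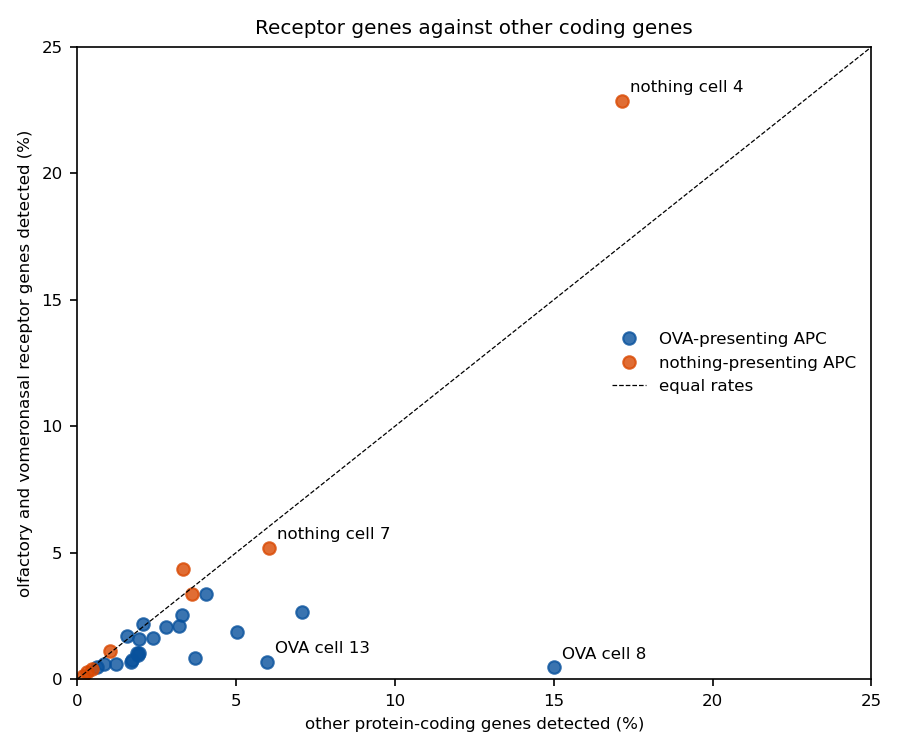
Each point is 1 library, with the share of 20549 other protein-coding genes detected (%) on the horizontal axis and the share of 1464 olfactory and vomeronasal receptor genes detected (%) on the vertical axis. Above the line of equal rates lie 5 libraries, nothing cells 1, 4 and 8 and OVA cells 2 and 18, with nothing cell 4 at 22.9% of receptor genes against 17.1% of other genes, and OVA cell 8 lies near the horizontal axis.

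Neutrophil markers were the set of another spleen cell type found in most cells of both groups. At least 1 of 9 neutrophil markers was detected in 15 of 21 OVA cells (71.4%, 95% interval 47.8% to 88.7%) and 5 of 8 nothing cells (62.5%, 24.5% to 91.5%). S100a8 or S100a9, abundant neutrophil transcripts, were detected in 13 of 21 (61.9%) and 5 of 8 cells (62.5%), and the 18 libraries included OVA cells 5, 9 and 16 with T cell receptor constant transcripts. Monocyte and macrophage markers were detected in 11 OVA and 2 nothing cells, erythroid markers in 6 and 2, T cell markers in 10 and 2, dendritic cell markers in 3 and 2, B cell markers in 1 and 3, and plasma cell markers in 1 and 2. MHC class II genes were detected in nothing cell 7 alone (Cd74 at 41.8 TPM) and NK cell markers in nothing cell 4 alone. Platelet markers were detected in 1 and 0 cells, fibroblast markers in 1 and 3, CD4 T cell markers in 1 and 1, CD8 T cell markers in 1 and 0, and OT-1 receptor segments in 4 and 1. Nothing cell 4 was among the nothing cells with markers of every set found in that group except MHC class II. Without it the monocyte and macrophage, erythroid, T cell, dendritic cell and plasma cell sets were each found in 1 of 7 nothing cells, the B cell and fibroblast sets each in 2 of 7, the neutrophil set in 4 of 7, and the NK cell, CD4 T cell and OT-1 segment sets in 0 of 7. The OVA cell with CD4 T cell markers was cell 8. Among these sets the 1 kept fibroblast marker lay below the random range (difference -1.05, percentile 0.695, or 2.62 without OVA cell 9). With size factors the difference was -0.22 (percentile 1.86). Without the filter on low values 3 fibroblast markers were lower and 1 higher, inside the random range (median -0.36, percentile 4.85).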

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

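All tests of explanations in this part were chosen after the results were seen. The comparison of each library with its group covered 23 measures in the 8 nothing cells, of which 13 had 1 library far from the others, 10 of them in nothing cell 4. The cut would pick 1 such library in about 20 groups by chance if values were normally distributed, which these are not. Effector cytokine scores, at 0 in 7 of 8 nothing cells, had to pass it. That rate therefore does not hold here, and measures of one library are not independent.

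Nothing cell 4 had 6385 genes detected, against 2364 in the next library. It also stood apart with 335 olfactory and vomeronasal receptor genes detected, 76.1% of TPM in its top 50 entries (the lowest of the group), 1.34% of TPM at ribosomal RNA locus models and 5.5% at mitochondrial-copy models. The scores on which it stood apart were early activation surface molecules (3.36), effector cytokines and chemokines (2.97), chaperones (2.54), naive and quiescence genes (3.69) and adhesion and migration genes (1.999). It was also the highest nothing cell, by a smaller gap, for interferon response (3.10), ribosome biogenesis (1.80), cell cycle (1.25) and T cell receptor signalling genes (1.14). Nothing cell 7 stood apart with 53 ribosomal protein genes detected, 0.642% of TPM in ribosomal protein genes and a cholesterol synthesis score of 1.54.

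The breadth of nothing cell 4 was weighed against a richer messenger RNA yield. Only 21 of 93 ribosomal protein genes were detected in it, against 79 in OVA cell 8, which argues against a larger recovery of messenger RNA than in OVA cell 8. The medians were 19 in OVA cells and 5 in nothing cells, so a larger recovery than in most libraries stays open. Olfactory and vomeronasal receptor genes, which T cells are not known to use, were detected at 1.34 times the rate of other protein-coding genes, so reads from genomic DNA may account for part of its list, which includes Il2, Tnf and Cd4. This ratio is not particular to the library, since it was 1.32 in nothing cell 8, at least 0.702 in every nothing cell (mean 0.997), 0.580 on average in OVA cells and lowest in OVA cell 8 (0.0318). Antigen absence by itself is argued against, since the other 7 nothing cells share it and had 92 to 2364 genes, and a response of this cell alone was not tested.

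Of the 15 lists of T cell programmes, the 4 above the random range in OVA cells (chaperone, adhesion and migration, T cell receptor signalling, negative feedback) were weighed next. Scaling by the share of spike-ins in TPM is argued against as the whole cause for the chaperone and negative feedback lists. With spike-ins left out, these lists and T cell receptor signalling lay at percentile 98.6 or above. Medians relative to all kept genes were then 0.69 against 0.79 as deposited (chaperone) and 1.42 against 1.17 (negative feedback). For T cell receptor signalling they were 0.69 against 0.56. Rescaling cannot restore genes listed at 0 in libraries that were mostly spike-ins, so that effect of the share stays open. Without libraries over 90% spike-ins, T cell receptor signalling lay inside the random range and the other 3 lists above it. The spike-in share therefore stays open for T cell receptor signalling. It also stays open for the adhesion list, which fell to percentile 93.6 with spike-ins left out. The relative median of that list was 0.54 against 0.68, since its own median stayed near 0.79 while that of all kept genes rose by 0.15. A higher messenger RNA yield in OVA libraries, whatever the gene, may account for them, since housekeeping genes were higher too. Olfactory and vomeronasal receptor genes were detected at a lower relative rate in OVA cells (0.580 against 0.997). Housekeeping genes, at 1.71, lay 1.18 above the median of their level-matched random lists. The chaperone and adhesion lists lay 0.76 above theirs, T cell receptor signalling 0.66 and negative feedback a larger 1.38. That 1.38 rests on 3 genes that passed the filter through OVA cells only. The 10 lists inside the random range lay from -0.11 (early activation surface molecules) to 0.87 (effector cytokines) relative to the medians of their own random lists. Ribosome biogenesis lay at -0.0009 and cell cycle at 0.06, so a rise was not seen in every list. A larger share of T cell RNA stays open for receptor signalling, which lay at percentile 92 without its 4 T cell markers (those 4 lay at 99.96). Without the filter on low values the list without T cell markers lay at 99.59, so the 4 markers alone do not settle this. Contact with antigen was not tested, because each group is 1 sample.

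S100a8 and S100a9 in libraries from cells called T cells were the last pattern. An equal amount of free RNA in every tube stays open, since S100a8 relative to spike-ins in OVA cell 8 was 6.76 times that of the next library, but this speaks against it only if every tube got the same amount of spike-in RNA, which is not given. Neither gene was detected in OVA cell 13 (2273 genes detected) or OVA cell 19 (1581 genes). An equal amount would not predict that, but a gene at 0 may be a failed estimate. OVA cell 8 had 6 of 9 neutrophil markers (S100a8 at 8910 TPM, S100a9 at 9320, Camp at 1088) and no T cell receptor constant transcript, so a neutrophil in the tube is a candidate source, but it also had Thy1 (15.0 TPM), Lcp2 (41.4 TPM) and markers of CD4 T cells, dendritic cells, monocytes and erythroid cells, so RNA of more than 1 cell stays open. OVA cells 5, 9 and 16 were picked because all 3 had both T cell receptor and S100a8 or S100a9 transcripts, so this overlap tests nothing. A neutrophil in place of a T cell, free RNA of unequal amount and 2 cells in a tube stay open there.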

How the results depend on the processing

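Rescaling without spike-ins, the subsets by library and cell numbers, and leaving cells out for genes detected, composition and cell type markers, and leaving shared T cell markers out of the receptor signalling list, were chosen after seeing the data. Of 592 alternative list medians 555 kept their sign, and of 2914 alternative differences of named genes 2792 did. Over the alternatives other than leaving out 1 cell, the chaperone list lay above the random range in 12 of 14, negative feedback in 12 of 13, T cell receptor signalling in 9 of 13 and adhesion in 5 of 14. Without the filter on low values, immediate early, activation transcription factor, glycolysis, naive and quiescence and cell cycle lists also lay above the range (98.8 or more). T cell receptor signalling lay at percentile 96.8 without cells under 1000 genes and 96.9 without libraries over 90% spike-ins. With medians over cells every list median was 0, since most entries are 0. Detection in at least 10 cells kept 293 genes, and the median difference per gene was then 1.14, the chaperone genes median difference 2.45 on 4 members and the adhesion and migration genes median difference 3.31 on Actb alone, which follows from the smaller set of abundant genes. That filter left no member of most lists, so those have no value. With each cell left out, the count of OVA cells above every nothing cell on the early activation surface molecules score ranged from 1 to 3, on the activation transcription factors score from 3 to 8, and on the naive and quiescence genes score from 0 to 2. As a share of members listed, the early activation surface molecules score gave 1. The cause was not tested for these score counts. Cells with fewer than 1000 genes left out gave -890 for genes detected per cell. Depth is unknown, so a gene listed at 0 is not shown to be absent.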

Other observations

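The genes in this part were chosen after their values were seen. OVA cell 13 had the clearest T cell profile of the 29 libraries. Beside its receptor transcripts it had 2310 TPM of Ccl5, a chemokine of memory and effector CD8 T cells, 4670 TPM of B2m, the light chain of class I MHC and 201 TPM of Nfkbid, a regulator of NF-kappaB. Icam1, an adhesion ligand, was at 220 TPM in OVA cell 13 and 49.2 TPM in OVA cell 9. The orphan nuclear receptor Nr4a2, an immediate early gene, was at 43.3 and 45.0 TPM in the same libraries and in no other, and Ccl5 was at 467 TPM in OVA cell 9.

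OVA cell 8 combined neutrophil and proliferation transcripts. Ngp was at 390 TPM, Fcer1g at 526 TPM, Ccl3 at 279 TPM and Mki67 at 92.8 TPM. Haemoglobin genes were detected in 6 of 21 OVA cells and 2 of 8 nothing cells, with Hba-a1 at 520 TPM in OVA cell 20 and 249 TPM in nothing cell 5.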
